A study of Mus musculus with 8 samples.

How the data were processed

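Bone marrow cells of 9 mice were sorted on c-kit, labelled with mouse-specific hashtag antibodies and sequenced with 10x 3' v3 chemistry on 4 lanes, per the labels. The 8 samples of the series are the 4 gene expression libraries and the 4 hashtag libraries of these lanes, each pooling mice, so the mouse and not the library was the replicate. The deposited hashtag key and cell metadata gave each cell's mouse and each mouse's group, JAK2 mutant (6 mice) or WT (3 mice). No source used here gave a treatment factor, a sorted fraction per mouse or mouse sex, so the planned interaction of genotype and treatment was not run.

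The main values were estimated counts of UMIs per gene and cell, not scaled, as deposited by the authors. Per the submitters' processing notes, FastQC 0.11.5, STAR (version not given), R 4.2.2 and the mm10 mouse genome were used. The settings of barcode and UMI counting, the cell filters and the annotation release are not given in the sources used here. Of the nonzero entries 6.30% were not whole numbers (tolerance 1e-06) and held 19.1% of the UMIs, so the counts were treated as estimated, summed and rounded to whole numbers before each test. How UMIs that fit several genes were shared out affects genes with near-identical copies. The deposited hashtag columns held log2 of the hashtag count plus 1, by their values. The cluster numbers (10 clusters and finer ones), the closest reference profile and the cell cycle phase of each cell were used as deposited by the authors, and the methods behind them are not given in the sources used here.

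The deposited matrix held 55493 features, of which 349 had no symbol (0.0501% of UMIs) and were kept under their identifiers. Its cells had at least 1533 UMIs and 1001 genes and at most 9.93% mitochondrial UMIs, and no further filter was applied. No doublet caller was run here, and whether doublets had been removed is not given in the sources used here. Median mitochondrial shares per mouse ran from 1.56% to 2.41%. Gene positions were taken from the GENCODE vM21 annotation of mm10.

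Counts were summed per mouse over all cells, and per mouse and cluster for mice with at least 20 cells. Differences were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with both groups in 1 model. Log2 fold changes are mutant minus WT and CPM, on TMM-adjusted library sizes, are means per group ± SD over mice. Clusters 1, 2, 3 and 5 were described in full: the stem cell-like cluster and the 3 with the most cells in their thinnest mouse. The other clusters are given as counts. Shares of cells and of phases were compared between mice by exact two-sided permutation tests over the 84 splits of 9 mice into 6 and 3, adjusted over the shares of a family. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scanpy 1.11.5 was used. The inverted share of the transgene carries 95% Wilson intervals, which cover counting error only.

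The tests, the gene lists, the cluster markers and the rule for named genes were set before the data were examined. The rule took, among genes with an adjusted p under 0.05, log2 CPM of at least 4 and no overlap between groups, the 8 largest rises and 8 largest falls in all cells and 4 and 4 in each main cluster. It added up to 4 members of each list by smallest p, and Socs2, Jak2, Cish, Socs1, Socs3, Pim1 and Irf7 whatever their p. Some genes the rule names are not reported here. Ccnd1 and Hsp90aa1 in all cells and Id1 in cluster 2 were named after their values were seen. The 24 lists, each reported for all cells, held markers of cell types and genes of signalling responses, cell cycle, metabolism, stress and sex-linked genes. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) and adjusted over the 24 lists. In the text, "adjusted p with an estimated correlation" is camera with the correlation estimated from the data. The lists were also tested with fry.

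Shares were compared between groups only for clusters with at most 1 of their 10 leading genes changed inside the cluster, a limit set after the data were seen. It left clusters 3, 6, 9 and 10 and took out 6 clusters whose comparison had been planned. Of these 6, clusters 1, 4 and 7 had a permutation adjusted p of 0.0397, with 4, 5 and 7 leading genes changed inside. Their shares were 31.1% of mutant against 19.2% of WT cells, 9.68% against 6.69% and 5.17% against 8.28%. Shifted cluster borders were not excluded for them. Nor were they for clusters 3, 6, 9 and 10, where few calls can also reflect low power.

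The alternatives were DESeq2 1.42.0, other scalings, no filter or at least 50 counts in every WT mouse, a change of at least 2-fold, a higher UMI minimum that left out 41 cells, 10 or 50 cells per mouse, equal cell numbers per mouse, the lane as a block and each mouse left out in turn. Chosen after seeing the data were lanes 2 and 3 alone, a term for hashtag 3 (whose mice, mutant 1, 2 and 3 and WT 1, were those with Y-linked transcripts), all cells without cluster 10, other definitions of the stem cell class (closest reference profile, or each of fine clusters 1, 4, 9 and 11) and phase scores of cells thinned to 5000 UMIs, which left out 2713 mutant and 386 WT cells. The lane is a shared technical batch per the deposited hashtag key, and values with the lane as a block stand beside the results they change. Lanes 1 and 4 held only mutant mice, so the lane block rests on mutant 2 and 5 against the WT mice. A call lost under it can reflect fewer mice and does not by itself show a lane effect. Deviations of same-lane mice of different groups from their group means had correlations of -0.273, 0.159 and 0.106.

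The tests were checked on simulated counts with 200 changed genes. In all cells, 55.4%, 77.8% and 95.4% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, among 17416 genes in the fit. In clusters 1, 2, 3 and 5, 76.1%, 82.8%, 40.3% and 59.4% of 1.5-fold changes and 94%, 92.4%, 77.3% and 85.1% of 2-fold changes were recovered, in fits of 12965, 13194, 12189 and 11738 genes. Of the genes called, 9.77% in all cells and 6.06%, 8.33%, 5.13% and 7.26% in those clusters had no simulated change. In the same simulations camera called a list shifted 1.5-fold in every fit. Of the 23 other lists it called 2 in cluster 1, 1 in cluster 2, 1 in cluster 5 and none in all cells or cluster 3.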

Results

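Transcripts were counted in single c-kit+ bone marrow cells from 6 mice carrying an inducible JAK2-V617F transgene (called mutant) and 3 wild-type (WT) mice. JAK2-V617F is the activating kinase mutation typical of human myeloproliferative neoplasms. Per the labels, the transgenic mice received 2 mg tamoxifen (100 mg/kg) on 5 days. Whether the WT mice received it was not stated. Cells came from stem cell, stem and progenitor, or Sca-1-negative myeloid progenitor gates, and the mix of gates in each mouse was not given. The series title asks about loss of Socs2 and the response to interferon alpha, but the only group given for the cells used here was the genotype of their mouse. Mutant was therefore compared with WT, in all cells of a mouse and in the deposited clusters, and no effect of treatment or Socs2 loss was tested.

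The 39940 cells held 605600734 UMIs, with a median of 12773 UMIs and 3470.5 genes per cell. Mutant 1 to 6 gave 8500, 5861, 5229, 1922, 3340 and 5620 cells with 114836620, 91784687, 81261334, 27901919, 46972867 and 89119774 UMIs. WT 1 to 3 gave 2976, 3804 and 2688 cells with 46925484, 67523304 and 39274745 UMIs. Median UMIs per cell ran from 10063 in mutant 1 to 16484.5 in WT 2. Lane 1 held mutant 1 and 4, lane 2 mutant 2 and WT 2, lane 3 mutant 5, WT 1 and WT 3, and lane 4 mutant 3 and 6, so 2 of the 4 lanes held mice of both groups.

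The deposited metadata gave 10 clusters, which were named from marker lists fixed before the data were examined. Cluster 1 (11819 cells, led by Hlf and Procr) was stem cell-like, cluster 2 (6303 cells, led by F13a1, Clec7a and Csf1r) monocyte-like, cluster 3 (5868 cells, led by Ngp, Camp and S100a9) neutrophil-like and cluster 4 (3513 cells) granulocyte progenitor-like. Cluster 6 (2422 cells, led by Pf4 and Gp1bb) was megakaryocyte-like, cluster 8 (1905 cells, led by Prss34 and Prg2) basophil, mast cell and eosinophil-like, and cluster 10 (1201 cells, led by Rhd, Cldn13 and Ermap) erythroid-like. Clusters 5 (3515 cells, led by Cxcr2 and Cd34), 7 (2245 cells) and 9 (1149 cells, led by Igkc and Jchain) stayed unnamed. Some leading genes differed between mutant and WT cells inside their own cluster, among them Ly6a in cluster 1, F13a1 and Itga1 in cluster 2 and Cxcr2 in cluster 5.

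The human JAK2 transgene was read in every mutant mouse and at background in WT mice. In all cells summed, its exons 3 to 12 gave 25.4 ± 2.83 CPM (UMIs scaled to each mouse's TMM-adjusted total; SD, n = 6) in mutant and 0.215 ± 0.0299 CPM (SD, n = 3) in WT mice. These rest on 816 to 3315 UMIs per mutant and 8 to 17 per WT mouse. The log2 fold change was 6.84 (SE 0.15, edgeR adjusted p = 4.36e-12). Exons 13 to 25 read in the forward orientation gave 13.1 ± 1.43 against 0.254 CPM, and the same exons read as inverted gave 1.42 ± 0.20 against 0.0169 CPM. The inverted orientation is that of a transgene not switched on by the recombinase. It made up 9.87% ± 1.72 of the exon 13 to 25 UMIs (SD, n = 6, range 7.94% to 12.8%). The 95% Wilson intervals of the mice together spanned 5.76% to 15.1%. Endogenous Jak2 (ENSMUSG00000024789, chromosome 19, 29251828 to 29313080, plus strand, mm10) was lower in mutant mice, at 17.0 ± 1.32 against 20.7 ± 2.84 CPM (log2 fold change -0.28, edgeR adjusted p = 0.0290). The Jak2 call was lost with the lane as a block (-0.10, edgeR adjusted p = 0.396), without cluster 10 cells (-0.20, adjusted p = 0.169) and without mutant 1, 3 or 6 or WT 1 or 3 (adjusted p 0.0523 to 0.180). Reads shared by the human and mouse gene could not be separated. Inside clusters 1, 2, 3 and 5, Jak2 changes of -0.08, -0.07, -0.27 and -0.14 did not pass (edgeR adjusted p = 0.772, 0.763, 0.323 and 0.720).

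Socs2, a STAT5-induced suppressor of cytokine signalling, was much higher in mutant cells. The gene (ENSMUSG00000020027) spans chromosome 10, 95385362 to 95417180, minus strand (mm10). In all cells it measured 16.1 ± 2.74 CPM in mutant and 1.52 ± 0.460 CPM in WT mice (log2 fold change 3.38, SE 0.22, edgeR adjusted p = 6.35e-06). In stem cell-like cluster 1 it measured 78.0 ± 7.29 against 5.46 ± 0.239 CPM, a 14.3-fold difference (log2 fold change 3.84, SE 0.13, edgeR adjusted p = 1.74e-15). Every mutant mouse lay above every WT mouse in both populations. In cells closest to a long-term stem cell profile it measured 131 ± 33.0 against 34.2 ± 8.86 CPM, 3.82-fold (2.00, edgeR adjusted p = 0.000954). Socs2 rose in megakaryocyte-like cluster 6, at 30.004 ± 2.71 against 5.13 ± 1.44 CPM (2.51, edgeR adjusted p = 8.23e-10). In cluster 7 it stood at 15.4 ± 4.08 against 1.81 ± 1.07 CPM (2.85, edgeR adjusted p = 9.27e-07). In cluster 5 its levels were low, 2.90 ± 1.55 against 0.530 ± 0.106 CPM, and the groups overlapped (2.49, edgeR adjusted p = 0.0201). That call was lost with the lane as a block (1.71, edgeR adjusted p = 0.410) and without WT 1, 2 or 3 (adjusted p = 0.0821, 0.132 and 0.109). The difference between the changes in clusters 5 and 1 did not pass (-1.31, edgeR adjusted p = 0.575). In cluster 9 Socs2 did not pass (0.44, edgeR adjusted p = 0.916), and in clusters 2, 3, 4, 8 and 10 it lay below the filter on low counts.

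**Figure D1:**
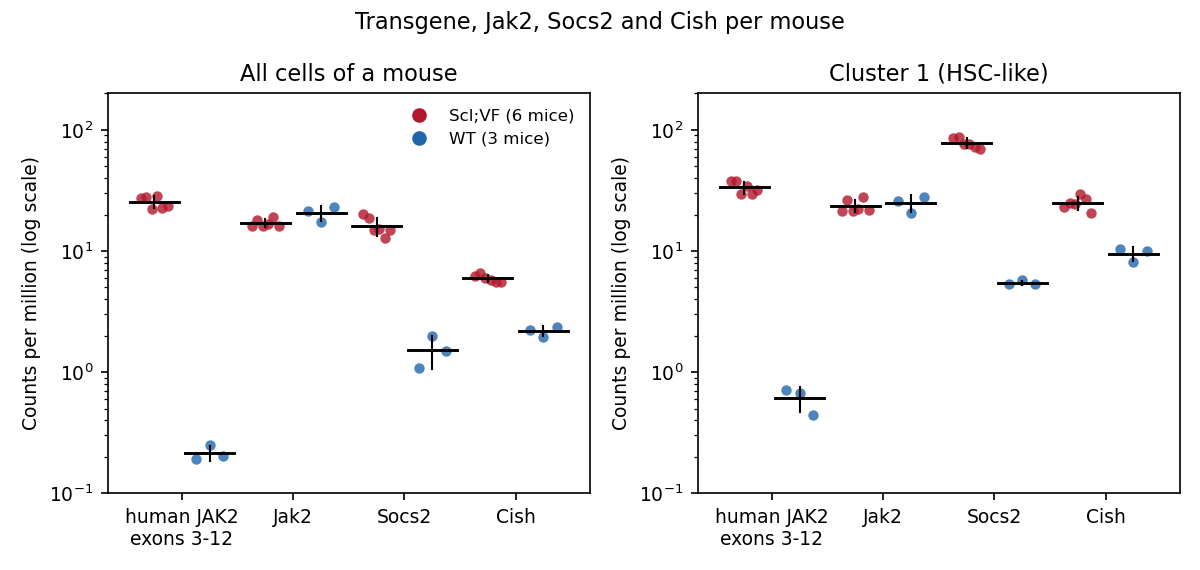
CPM (UMIs scaled to each mouse's TMM-adjusted total, log axis) of human JAK2 exons 3 to 12, Jak2, Socs2 and Cish in each mouse, for all cells and for cluster 1; each point is a mouse, the line is the mean and the bar the SD. Mutant mice stand above WT mice for the transgene, Socs2 and Cish.

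Some other STAT targets rose. The test of the difference between clusters passed for Socs1 and Pim1 (cluster 1 against clusters 2 and 3, and for Pim1 also against cluster 5). It did not pass for Cish or Socs3 (cluster 1 against clusters 2, 3 and 5, edgeR adjusted p 0.0642 to 0.974). Cish (ENSMUSG00000032578, chromosome 9, 107296026 to 107302784, plus strand), another STAT5-induced inhibitor, rose in all cells (5.95 against 2.19 CPM, 1.45, edgeR adjusted p = 2.09e-07) and in cluster 1 (25.001 against 9.51 CPM, 1.37, adjusted p = 5.97e-07). Socs3 (ENSMUSG00000053113), the inhibitor of gp130 and G-CSF receptor signalling, rose in all cells (2.43, edgeR adjusted p = 9.78e-07) and in clusters 1 (1.55, adjusted p = 0.00206), 2 (2.85, adjusted p = 0.000421), 3 (3.13, adjusted p = 0.00792) and 5 (2.77, adjusted p = 4.04e-06). The cluster 3 call was lost without WT 1 or 2 (edgeR adjusted p = 0.0514 and 0.0643) and with lanes 2 and 3 only (adjusted p = 0.107). Socs1 rose in all cells (0.69, edgeR adjusted p = 0.000385) and cluster 1 (0.88, adjusted p = 0.00534). The cluster 1 call was lost with the lane as a block (edgeR adjusted p = 0.0768), without WT 3 (adjusted p = 0.0527) and in fine clusters 1 and 11 alone (adjusted p = 0.675 and 0.585). Its changes in clusters 2, 3 and 5 did not pass (-0.11, -0.35 and 0.59, edgeR adjusted p = 0.843, 0.506 and 0.309). The kinase gene Pim1 (ENSMUSG00000024014, chromosome 17, 29490753 to 29496112, plus strand) rose in all cells, at 176 ± 24.1 against 72.8 ± 21.0 CPM (1.27, edgeR adjusted p = 0.00366, lost with the lane as a block at 0.0693). It rose in clusters 2 and 3 (1.498 and 1.495) and did not pass in cluster 1 (0.64, edgeR adjusted p = 0.247). In cluster 5 every mutant mouse lay above every WT mouse, and Pim1 did not pass by edgeR (1.02, edgeR adjusted p = 0.0687) but passed by DESeq2 (adjusted p = 0.000448) and with a term for hashtag 3 (1.12, edgeR adjusted p = 0.0115). Cish in cluster 5 rose by 1.42 (edgeR adjusted p = 0.0167). This call was lost by DESeq2 (adjusted p = 0.0834), with the lane as a block (edgeR adjusted p = 0.345) and without any WT mouse (edgeR adjusted p 0.0645 to 0.0909). In cluster 2 Cish did not pass (0.27, edgeR adjusted p = 0.742).

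**Figure D2:**
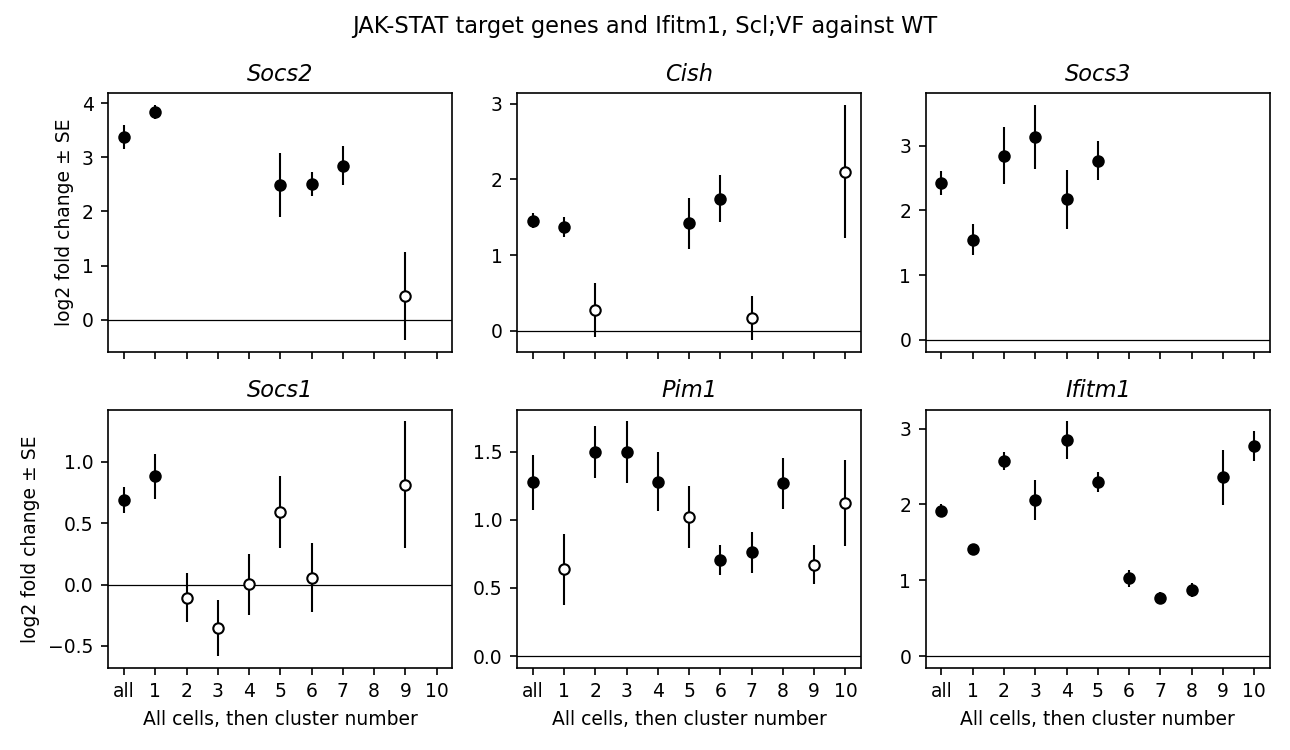
Log2 fold change (mutant minus WT) with its SE for Socs2, Cish, Socs3, Socs1, Pim1 and Ifitm1 in all cells and in each of clusters 1 to 10 where the gene was tested; filled points have an edgeR adjusted p under 0.05. Socs2 is filled in all cells and in clusters 1, 5, 6 and 7.

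In all cells summed, transcripts of red cell precursors were far lower in mutant mice. Car1, erythroid carbonic anhydrase (ENSMUSG00000027556, chromosome 3, 14766216 to 14808368, minus strand), measured 29.1 ± 13.1 CPM in mutant and 663 ± 35.0 CPM in WT mice, a 22.8-fold difference (log2 fold change -4.51, SE 0.38, edgeR adjusted p = 0.000190). Ifitm1, an interferon-induced transmembrane protein also used here as a stem cell marker (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825, plus strand), stood at 827 ± 89.5 against 219 ± 12.1 CPM (1.92, SE 0.09, edgeR adjusted p = 1.55e-08). Together 3926 of 17674 genes changed, 1889 up and 2037 down. Without the cells of cluster 10 the count was 1247, with the lane as a block 2349, and without WT 3 it was 2572.

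Beside the transgene, the genes chosen by size of rise and present at log2 CPM of at least 4 were Ifitm1, Prg2, Serpina3g, Pim1, Rgs1, Ly6a and Egr1. Those chosen by size of fall were Rhd, Hba-a1, Ermap, Car1, Mt2, Hbb-bs, Klf1 and Ctse. By that rule all 6 mutant mice lay on 1 side of all 3 WT mice, here and in each cluster. Serpina3g rose from 24.1 to 59.8 CPM (1.31, edgeR adjusted p = 2.54e-06), with reads possibly shared within its gene family, and the growth factor-induced Egr1 from 12.5 to 26.0 CPM (1.06, adjusted p = 0.000858). Rgs1, a regulator of G protein signalling (1.15, edgeR adjusted p = 0.00858), and Ly6a, which encodes Sca-1 (1.11, adjusted p = 0.0155), lost their calls with the lane as a block (adjusted p = 0.123 and 0.167) and without cluster 10 cells (adjusted p = 0.0550 and 0.0881). Prg2, eosinophil major basic protein (1.34, edgeR adjusted p = 0.0412), lost its call with the lane as a block (adjusted p = 0.195), with a term for hashtag 3, without the filter, without cluster 10 cells, and without any mouse except mutant 2 or 4 (adjusted p 0.0660 to 0.133). The erythroid transcription factor Klf1 fell by 3.52 on the log2 scale (60.7 to 5.42 CPM, edgeR adjusted p = 9.63e-05). The Rh antigen gene Rhd fell by 5.51 (edgeR adjusted p = 0.000345), Ermap by 4.85, Mt2 by 4.38 and the protease gene Ctse by 3.40 (adjusted p = 0.000366, 0.000336 and 3.73e-06). Globin genes Hba-a1 and Hbb-bs, whose reads can be shared with near-identical copies, fell by 5.02 and 3.56 (edgeR adjusted p = 0.00244 and 0.0148) and lost their calls with the lane as a block (adjusted p = 0.101 and 0.113). Without cluster 10 cells, Car1 alone of these 8 kept its call (-2.19, edgeR adjusted p = 0.0289). Irf7, an interferon pathway gene, was lower with overlapping groups (-0.71, edgeR adjusted p = 0.00656). Its call was lost with the lane as a block (edgeR adjusted p = 0.0566) and without cluster 10 cells (adjusted p = 0.0617).

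Among the 24 lists, 16 passed camera in all cells, and 3 of these held with an estimated correlation between genes. Of 24 measured erythroid genes 23 fell, 23 also when adjusted over the list alone. Their median was -3.21 (camera adjusted p = 5.53e-83, adjusted p = 0.00704 with an estimated correlation). Of 19 genes of haem synthesis and globins 16 fell, 17 adjusted over the list alone. Their median was -0.88 (camera adjusted p = 1.45e-42, adjusted p = 0.00389 with an estimated correlation). Without cluster 10 cells the erythroid median was -1.05 and still passed (camera adjusted p = 1.56e-11), and the haem median was 0.002 and did not (camera adjusted p = 0.737). Of 19 JAK-STAT5 targets 9 rose, among them Socs2, Cish, Socs3 and Pim2 (1.15), and Ccnd1, cyclin D1, fell by 1.66 (adjusted over the list alone 9 and 2). Their median was 0.25 (camera adjusted p = 6.91e-07, adjusted p = 0.00704 with an estimated correlation). Negative regulators of JAK-STAT signalling, which share 4 genes with that list, had 5 of 16 members up and 3 down, 5 and 4 adjusted over the list alone. Their median was 0.05 (camera adjusted p = 0.00109, adjusted p = 0.0908 with an estimated correlation) and 0.03 without mutant 2 or WT 2 or 3.

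Some markers of stem cells, megakaryocytes and neutrophils rose, and some lymphoid-primed markers fell. Sums over all cells also follow the mix of cells, as with the larger share of cluster 1 in mutant mice (31.1% against 19.2%). In these sums, a change of mix was not separated from changes within cells. Of 24 stem cell genes 16 rose, among them Esam (1.16), and 2 fell, Mllt3 (-0.75) and Clca3a1 (-0.62), with the same counts adjusted over the list alone. Their median was 0.51 (camera adjusted p = 4.91e-10, adjusted p = 0.225 with an estimated correlation). Of 23 megakaryocyte genes 9 rose, 12 adjusted over the list alone, among them Serpine2 (0.44) and Itgb3 (0.49). Their median was 0.44 (camera adjusted p = 2.56e-05, adjusted p = 0.313 with an estimated correlation). Of 20 neutrophil and granulocyte progenitor genes 7 rose, 8 adjusted over the list alone, among them the granule protein genes Ctsg (0.64) and Ms4a3 (0.75). Their median was 0.29 (camera adjusted p = 0.00180, adjusted p = 0.445 with an estimated correlation) and 0.16 to 0.83 without WT 1, 2 or 3, a call lost without cluster 10 cells (camera adjusted p = 0.0766). Of 16 lymphoid-primed genes 7 fell, 8 adjusted over the list alone, among them the regulators Satb1 (-0.46) and Notch1 (-0.35). Their median was -0.37 (camera adjusted p = 0.00777, adjusted p = 0.261 with an estimated correlation, camera adjusted p = 0.0662 with the lane as a block). Of 9 B cell genes only Ms4a1 fell (-2.94, mean 0.0367 against 0.277 CPM), in both counts. Their median was -1.28 (camera adjusted p = 0.0120, adjusted p = 0.445 with an estimated correlation, camera adjusted p = 0.133 with the lane as a block). Of 20 monocyte and dendritic cell genes 3 fell in both counts, Zbtb46 (-2.81), Irf8 (-0.45) and F13a1 (-0.37). Their median was -0.17 (camera adjusted p = 0.0128, adjusted p = 0.445 with an estimated correlation, camera adjusted p = 0.0889 without WT 3) and -0.37 without WT 1.

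Some cell cycle genes fell and most glycolysis genes rose in all cells. Of 30 genes of G2 and M phase 19 fell, 20 adjusted over the list alone, among them the proliferation marker Mki67 (-0.53). Their median was -0.18 (camera adjusted p = 1.49e-06, adjusted p = 0.313 with an estimated correlation). Of 30 S phase genes 13 fell, 16 adjusted over the list alone, among them cyclin E1 gene Ccne1 (-1.29). Their median was -0.14 (camera adjusted p = 2.56e-05, adjusted p = 0.313 with an estimated correlation), a call lost without cluster 10 cells (camera adjusted p = 0.557). Of 16 glycolysis genes 13 rose, among them pyruvate kinase gene Pkm (0.44) and glucose transporter gene Slc2a1 (0.53), and Hk1 fell (-0.31), with 15 and 1 adjusted over the list alone. Their median was 0.31 (camera adjusted p = 6.29e-05, adjusted p = 0.313 with an estimated correlation). Of 20 immediate early and heat shock genes 8 rose, among them Ier3 (0.92) and Junb (0.65), and Hsp90aa1 fell (-0.27), with 11 and 1 adjusted over the list alone. Their median was 0.52 (camera adjusted p = 2.56e-05, adjusted p = 0.313 with an estimated correlation). Of 19 genes of the TNF and NF-kB response 7 rose, 9 adjusted over the list alone, among them Icam1 (0.51). Their median was 0.28 (camera adjusted p = 0.00552, adjusted p = 0.313 with an estimated correlation), a call lost without cluster 10 cells (camera adjusted p = 0.440). Of 13 mitochondrially encoded genes 4 fell in both counts, among them mt-Nd1 (-0.34). Their median was -0.28 (camera adjusted p = 0.00777, adjusted p = 0.445 with an estimated correlation, camera adjusted p = 0.181 with the lane as a block). The other 8 lists did not pass. Of 45 type I interferon response genes 4 rose and 6 fell in both counts. Their median was 0.01 (camera adjusted p = 0.819), with Cmpk2 (-1.12), Oasl1 (-1.14) and Mx1 (-1.11) among those that fell. Of 18 genes of MHC class I presentation 4 rose and 1 fell in both counts (camera adjusted p = 0.158). Basophil, mast cell and eosinophil genes (4 of 15 up and 1 down in both counts) and endothelial and stromal genes (1 of 5 up, 3 adjusted over the list alone) each had camera adjusted p = 0.158. Nuclear genes of oxidative phosphorylation (3 of 28 down in both counts, camera adjusted p = 0.558), p53 targets (4 of 17 up and 3 down, 5 and 4 adjusted over the list alone, camera adjusted p = 0.819) and T and natural killer cell genes (1 of 10 up in both counts, camera adjusted p = 0.654) did not pass. Of 6 sex-linked genes edgeR called 0, and the count was 0 also when adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2 (camera adjusted p = 0.819).

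**Figure D3:**
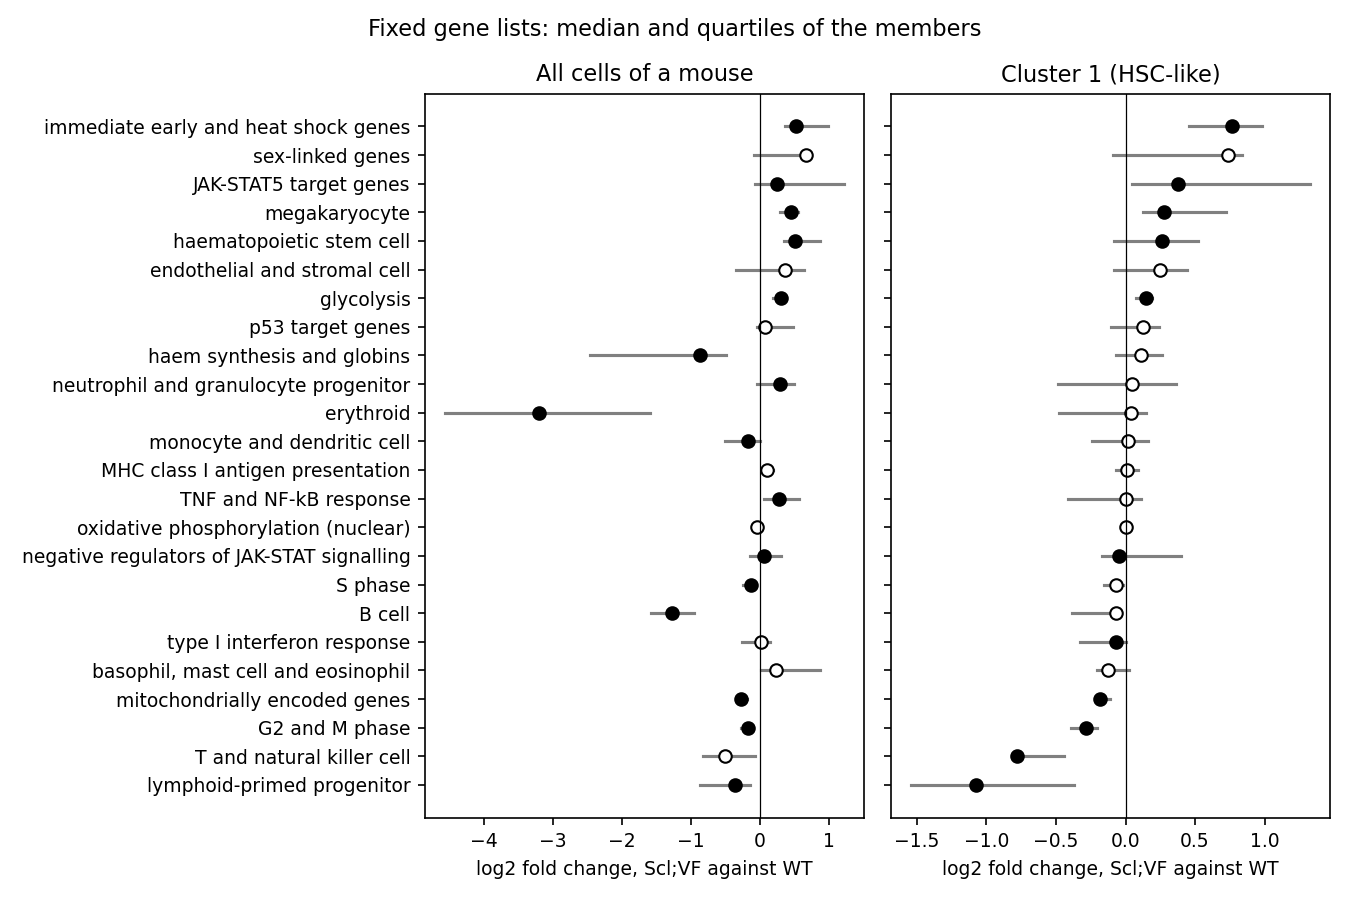
Median (point) and quartiles (bar) of the log2 fold changes (mutant minus WT) of each list's measured members, for 24 lists in all cells and in cluster 1; filled points have a camera adjusted p under 0.05. The erythroid list stands lowest in all cells, with a median of -3.21.

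In stem cell-like cluster 1, 8 of 18 JAK-STAT5 targets rose and 8 of 13 lymphoid-primed genes fell. Beside Socs2 and the transgene (33.6 against 0.609 CPM), the largest rises at log2 CPM of at least 4 were in 2 genes. The tight junction gene Tjp1 (ENSMUSG00000030516, chromosome 7, 65296165 to 65527781, minus strand) stood at 25.6 ± 3.41 against 5.21 ± 2.21 CPM (2.27, SE 0.20, edgeR adjusted p = 8.43e-07). Plxdc2 stood at 32.4 ± 2.79 against 8.54 ± 1.73 CPM (1.95, edgeR adjusted p = 6.75e-10). A large fall was in Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925, minus strand), at 11.4 ± 1.66 against 38.2 ± 8.39 CPM (-1.72, SE 0.13, edgeR adjusted p = 2e-08). Dntt, terminal deoxynucleotidyl transferase of lymphoid precursors, stood at 81.3 ± 26.3 against 241 ± 53.2 CPM (-1.60, edgeR adjusted p = 0.0253). Ighm, the immunoglobulin mu chain gene, stood at 31.2 ± 3.69 against 90.2 ± 10.3 CPM (-1.54, SE 0.09, edgeR adjusted p = 2.28e-10). The processed transcript Gm43305 fell too (-1.41, edgeR adjusted p = 0.00894). Dntt and Gm43305 lost their calls with the lane as a block (edgeR adjusted p = 0.377 and 0.284), and Dntt also without mutant 2, 3 or 6 or any WT mouse (adjusted p 0.0524 to 0.0992) and in fine clusters 1, 4 and 11 alone (adjusted p up to 0.485). In fine cluster 1 alone Ighm stood at -0.54 (edgeR adjusted p = 0.621). In cells closest to a short-term stem cell profile Ighm, Dntt and Gm43305 stood at -0.36, -0.18 and -1.10 (edgeR adjusted p = 0.747, 0.934 and 0.163). In those closest to a long-term stem cell profile Plxdc2, Tjp1, Cish and Ifitm1 stood at 0.48, 1.75, 0.90 and 0.33 (edgeR adjusted p = 0.485, 0.154, 0.242 and 0.758). Irf7 did not pass (-0.33, edgeR adjusted p = 0.315). Of 13100 genes 587 changed, 319 up and 268 down, against 203 with the lane as a block and 322 without WT 1.

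Of the lists, 11 passed in cluster 1, and 2 held with an estimated correlation. JAK-STAT5 targets had 8 of 18 members up and Ccnd1 down, 10 and 1 adjusted over the list alone. Their median was 0.38 (camera adjusted p = 3.27e-16, adjusted p = 0.00105 with an estimated correlation). Podxl (2.03) and Pim2 (1.19) rose beside Socs2. Of 13 lymphoid-primed genes 8 fell, 10 adjusted over the list alone. Their median was -1.08 (camera adjusted p = 7.57e-33, adjusted p = 0.00588 with an estimated correlation), including recombinase gene Rag2 (-2.87), cytokine receptor gene Flt3 (-0.96) and Notch1 (-1.08). In cells closest to a short-term stem cell profile the median of 10 members was -0.14 (camera adjusted p = 0.779). Stem cell genes had 6 of 24 up and Gcnt2 down, 12 and 2 adjusted over the list alone. Their median was 0.26 (camera adjusted p = 3.93e-06, adjusted p = 0.0646 with an estimated correlation), with Ifitm1 (1.41), the CD150 gene Slamf1 (1.23) and Esam (0.58) up. Megakaryocyte genes had 5 of 19 up, 10 adjusted over the list alone. Their median was 0.28 (camera adjusted p = 1.11e-06, adjusted p = 0.0646 with an estimated correlation), with F2rl2 (2.25), Vwf (0.86) and Itgb3 (0.76) up. In fine cluster 1 alone the stem cell and megakaryocyte medians were -0.015 and -0.019 (camera adjusted p = 0.219 and 0.244), and in fine cluster 9 alone -0.038 and 0.21 (camera adjusted p = 0.646 and 0.172). Immediate early and heat shock genes had 5 of 17 up, 13 up and 1 down adjusted over the list alone, with Egr1 (1.45) and Ier3 (0.82) up. Their median was 0.77 (camera adjusted p = 3.27e-16, adjusted p = 0.0646 with an estimated correlation). Negative regulators of JAK-STAT signalling had 4 of 16 up, 4 up and 1 down adjusted over the list alone, with a median of -0.05, a mean of 0.41 and a test upward (camera adjusted p = 6.55e-07, adjusted p = 0.0646 with an estimated correlation). Of 30 genes of G2 and M phase 14 fell, 23 adjusted over the list alone, among them Kif11 (-0.50) and Ube2c (-0.47). Their median was -0.28 (camera adjusted p = 9.82e-17, adjusted p = 0.101 with an estimated correlation).

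A further 4 lists passed in cluster 1. Of 16 glycolysis genes edgeR called 0, and 0 adjusted over the list alone, with 4 higher at an unadjusted p under 0.05 and 0 called by DESeq2. Their median was 0.15 (camera adjusted p = 0.0105, adjusted p = 0.327 with an estimated correlation, lost with the lane as a block at camera adjusted p = 0.219 and without WT 3 at 0.0944). Of 13 mitochondrially encoded genes edgeR called 0, and 0 adjusted over the list alone, at an unadjusted p under 0.05 or by DESeq2. Their median was -0.18 (camera adjusted p = 0.0278, adjusted p = 0.761 with an estimated correlation). With the lane as a block that median was 0.09 (camera adjusted p = 0.138), and without mutant 3, 4 or 6 or WT 1 or 3 the call was lost (camera adjusted p 0.0716 to 0.167). Of 3 T and natural killer cell genes Lck fell (-0.85) in both counts. Their median was -0.78 (camera adjusted p = 0.0243, adjusted p = 0.101 with an estimated correlation), a call lost without mutant 4, mutant 5, WT 2 or WT 3 (camera adjusted p 0.109 to 0.169). Of 44 type I interferon response genes 2 rose and 3 fell in both counts. Their median was -0.07 (camera adjusted p = 0.0278, adjusted p = 0.831 with an estimated correlation): Mx1 (-2.44), Ifi27l2a (-0.73) and Oas3 (-0.64) fell, and Ifitm3 (0.26) and Ly6a (0.52) rose. That call was lost with the lane as a block (camera adjusted p = 0.0714) and without mutant 2, 4 or 6 or WT 3 (camera adjusted p = 0.102, 0.0781, 0.0738 and 0.922), where without WT 3 the median was 0.02.

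In monocyte-like cluster 2, Ifitm1, Pim1 and the neutrophil protein gene Lcn2 rose and the ubiquitin ligase gene Nedd4 fell. Ifitm1 stood at 555 ± 59.8 against 93.0 ± 12.04 CPM (2.57, SE 0.12, edgeR adjusted p = 1.26e-06). Pim1 stood at 122 ± 18.8 against 42.5 ± 9.12 CPM (1.498, edgeR adjusted p = 0.00705, or 0.226 with the lane as a block). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252, minus strand) stood at 51.1 ± 6.04 against 20.7 ± 3.68 CPM (1.34, edgeR adjusted p = 2.82e-05). Nedd4 (ENSMUSG00000032216, chromosome 9, 72662346 to 72749852, plus strand) stood at 28.3 ± 1.90 against 53.5 ± 3.30 CPM (-0.92, SE 0.07, edgeR adjusted p = 7.36e-09). Biliverdin reductase gene Blvrb fell by 0.59 (edgeR adjusted p = 0.000579, or 0.137 with the lane as a block). Gm43305 fell by 1.08 (edgeR adjusted p = 0.0355). Its call was lost with the lane as a block (edgeR adjusted p = 0.411), with a term for hashtag 3, without the filter, and without any mouse except mutant 5 or WT 2 (adjusted p 0.0555 to 0.140). Itga1, also chosen by size, is a leading gene of the cluster and is given no weight here. Irf7 did not pass (-0.61, edgeR adjusted p = 0.441). Of 13454 genes 465 changed, 266 up and 199 down, against 84 with the lane as a block, 230 with equal cell numbers, 214 without WT 2 and 199 without WT 3.

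In cluster 2, 8 lists passed and none held with an estimated correlation. Of 16 glycolysis genes 3 rose, 10 adjusted over the list alone. Their median was 0.15 (camera adjusted p = 5.05e-05, adjusted p = 0.508 with an estimated correlation). Neutrophil and granulocyte progenitor genes had 5 of 19 up in both counts, among them Prtn3 (0.43) and Ms4a3 (0.47). Their median was 0.13 (camera adjusted p = 0.00393, adjusted p = 0.508 with an estimated correlation), 0.02 without mutant 3 and -0.04 without WT 2 (camera adjusted p = 0.0580). Stem cell genes had Ifitm1, Ly6a (0.85) and Hoxa9 (0.46) up of 16, with 3 up and 1 down adjusted over the list alone, a median of -0.05, a mean of 0.24 and a test upward (camera adjusted p = 0.000309, adjusted p = 0.281 with an estimated correlation). That median turned without WT 2 or 3 (up to 0.08). JAK-STAT5 targets had Socs3, Pim1, Tfrc (0.42) and Id1 (0.39) up and Ccnd1 (-2.06) down of 16, with 5 and 2 adjusted over the list alone. Their median was 0.15 (camera adjusted p = 0.0240, adjusted p = 0.281 with an estimated correlation), a call lost without mutant 3 or 6 (camera adjusted p = 0.0621 and 0.0687). Haem synthesis and globin genes had Tfrc up and 4 of 18 down, 1 and 5 adjusted over the list alone, among them Hbb-bs (-2.62). Their median was -0.03 (camera adjusted p = 0.0214, adjusted p = 0.281 with an estimated correlation), lost with the lane as a block (camera adjusted p = 0.0508) and without WT 1 (camera adjusted p = 0.103). Erythroid genes had 1 of 13 up and Blvrb down, 1 and 2 adjusted over the list alone. Their median was -0.59 (camera adjusted p = 0.00340, adjusted p = 0.528 with an estimated correlation), -0.33 without mutant 6 and -1.03 without WT 2. Under the lane block the median was 0.07 (camera adjusted p = 0.684). Of 16 immediate early and heat shock genes Ier3 rose (0.51), 2 adjusted over the list alone. Their median was 0.30 (camera adjusted p = 0.000811, adjusted p = 0.508 with an estimated correlation). Of 13 mitochondrially encoded genes 1 fell, 2 adjusted over the list alone. Their median was -0.28 (camera adjusted p = 1.83e-07, adjusted p = 0.397 with an estimated correlation).

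In neutrophil-like cluster 3, Ifitm1, the chaperone gene Clu, Pim1 and Fkbp11 rose and the adhesion gene Ncam1 and the microRNA gene Mir6236 fell. Fkbp11 stood at 168 ± 26.0 against 79.2 ± 7.14 CPM (1.08, edgeR adjusted p = 0.00180, or 0.167 with the lane as a block). Mir6236 (chromosome 9, 110281287 to 110281409, plus strand) stood at 47.0 against 77.4 CPM (-0.71, edgeR adjusted p = 0.000416). Gluconeogenic Fbp1 fell by 0.78 (edgeR adjusted p = 0.00428). The other calls each depended on single mice. Ifitm1 (34.8 ± 8.35 against 8.39 ± 0.999 CPM, 2.06, edgeR adjusted p = 0.0119) and Ncam1 (-0.89, adjusted p = 0.0133) lost theirs without any WT mouse (adjusted p 0.0577 to 0.0679 and 0.0570 to 0.0770) and with the lane as a block (adjusted p = 0.0601 and 0.0563). Clu (1.75, edgeR adjusted p = 0.0229) lost its call without mutant 6, WT 1 or WT 2 (adjusted p = 0.0550, 0.0853 and 0.127). Pim1 (1.495, edgeR adjusted p = 0.0226) lost its call without mutant 1, mutant 6, WT 2 or WT 3 (adjusted p 0.0564 to 0.0851). Both lost theirs with the lane as a block (edgeR adjusted p = 0.178 and 0.240). Lars2, a mitochondrial tRNA synthetase gene (-0.75, edgeR adjusted p = 0.0265), lost its call without mutant 1, mutant 4 or any WT mouse (adjusted p 0.0593 to 0.132) and with library size alone as scaling (adjusted p = 0.0507). With equal cell numbers per mouse Ifitm1, Clu and Lars2 did not pass (edgeR adjusted p = 0.0750, 0.0644 and 0.0501), nor did Lars2 with lanes 2 and 3 only. Irf7 did not pass (-0.59, edgeR adjusted p = 0.549). Of 12317 genes 150 changed, 97 up and 53 down, against 30 with the lane as a block, 78 with equal cell numbers and 341 by DESeq2. Without mutant 2 or 6 the count was 90 and 75, and without WT 1, 2 or 3 it was 60, 22 and 19.

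In cluster 3, 7 lists passed and none held with an estimated correlation. JAK-STAT5 targets had Socs3, Tfrc (0.56) and Pim1 up of 14, 4 adjusted over the list alone. Their median was 0.21 (camera adjusted p = 0.000246, adjusted p = 0.0729 with an estimated correlation). Immediate early and heat shock genes had Junb (0.49) and Jund (0.66) up of 16, 4 adjusted over the list alone. Their median was 0.41 (camera adjusted p = 0.000242, adjusted p = 0.418 with an estimated correlation). Glycolysis genes had Ldha (0.41) up of 16, 5 adjusted over the list alone. Their median was 0.14 (camera adjusted p = 0.00293, adjusted p = 0.392 with an estimated correlation). Stem cell genes had Ifitm1 and Hoxa9 (1.14) up of 14, 2 up and 1 down adjusted over the list alone. Their median was 0.12 (camera adjusted p = 0.0102, adjusted p = 0.392 with an estimated correlation, camera adjusted p = 0.134 with the lane as a block), and up to 0.41 without mutant 2 or WT 1, 2 or 3. For 3 lists that passed edgeR called 0 members. Of 32 type I interferon response genes 6 were lower adjusted over the list alone, 1 was higher and 12 lower at an unadjusted p under 0.05, and DESeq2 called 2 lower. Their median was -0.19 (camera adjusted p = 0.000880, adjusted p = 0.392 with an estimated correlation) and -0.33 without WT 1. Of 13 mitochondrially encoded genes 10 were lower adjusted over the list alone, 10 at an unadjusted p under 0.05 and 2 by DESeq2. Their median was -0.35 (camera adjusted p = 3.81e-07, adjusted p = 0.392 with an estimated correlation, camera adjusted p = 0.112 with the lane as a block). Of 30 genes of G2 and M phase 0 were called adjusted over the list alone, 2 were lower at an unadjusted p under 0.05 and DESeq2 called 0. Their median was -0.10 (camera adjusted p = 0.0399, adjusted p = 0.672 with an estimated correlation). With the lane as a block that median was 0.03 (camera adjusted p = 0.529), and the call was lost without mutant 1, 2, 4 or 6 (camera adjusted p 0.0541 to 0.358) and without WT 1, where the median was 0.08 (camera adjusted p = 0.362).

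In unnamed cluster 5, 7 of 17 neutrophil genes rose and 4 of 13 lymphoid-primed genes fell. Ifitm1 stood at 1715 ± 240 against 350 ± 13.5 CPM (2.30, SE 0.13, edgeR adjusted p = 2.7e-05). Lcn2 stood at 62.9 ± 14.0 against 14.1 ± 0.361 CPM (2.13, edgeR adjusted p = 0.00519). The short-chain fatty acid receptor gene Ffar2 (chromosome 7, 30818348 to 30823775, minus strand) stood at 67.8 ± 6.33 against 26.0 ± 4.39 CPM (1.41, edgeR adjusted p = 1.92e-09). Gm43305 fell by 1.19 (edgeR adjusted p = 1.63e-06), Ighm by 0.94 (adjusted p = 1.76e-06), the melanocortin receptor gene Mc5r by 0.93 (adjusted p = 3.04e-05) and F13a1, the A chain of coagulation factor XIII, by 0.99 (adjusted p = 0.0210). F13a1 lost its call without any WT mouse (edgeR adjusted p 0.0685 to 0.122), and Lcn2 without WT 2 (adjusted p = 0.0547). Irf7 did not pass (-0.99, edgeR adjusted p = 0.0677), but did without WT 1 (-1.25, adjusted p = 0.0294). Of 11890 genes 338 changed, 209 up and 129 down, against 82 with the lane as a block, 219 with equal cell numbers, 178 without WT 2 and 182 without WT 3.

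In cluster 5, 8 lists passed and 3 held with an estimated correlation. Neutrophil and granulocyte progenitor genes had 7 of 17 up in both counts, among them Ms4a3 (1.02) and the granule protease genes Prtn3 (0.61) and Elane (0.54). Their median was 0.18 (camera adjusted p = 1.88e-11, adjusted p = 0.0214 with an estimated correlation), 0.29 without WT 1, and down to 0.09 without mutant 2 or WT 2. Lymphoid-primed genes had 4 of 13 down, 7 adjusted over the list alone, namely Ighm, Satb1 (-0.77), Notch1 (-0.76) and Flt3 (-0.63). Their median was -0.65 (camera adjusted p = 6.58e-10, adjusted p = 0.0451 with an estimated correlation). JAK-STAT5 targets had 5 of 16 up, among them Socs3, Tfrc (0.73) and Id1 (1.19), and Ccnd1 (-1.85) and Ccnd2 (-0.31) down, 8 and 2 adjusted over the list alone. Their median was 0.36 (camera adjusted p = 1.31e-05, adjusted p = 0.0214 with an estimated correlation) and 0.14 without WT 3. Immediate early and heat shock genes had 4 of 16 up, 8 adjusted over the list alone. Their median was 0.73 (camera adjusted p = 9.49e-13, adjusted p = 0.107 with an estimated correlation). Glycolysis genes had 4 of 16 up, 9 adjusted over the list alone. Their median was 0.17 (camera adjusted p = 1.63e-05, adjusted p = 0.129 with an estimated correlation). Stem cell genes had Ifitm1 and Esam (2.10) up of 18, 4 up and 2 down adjusted over the list alone. Their median was 0.12 (camera adjusted p = 6.05e-05, adjusted p = 0.0735 with an estimated correlation), 0.07 without mutant 6 and 0.23 without WT 2. Genes of G2 and M phase had 4 of 30 down, 7 adjusted over the list alone. Their median was -0.16 (camera adjusted p = 2.86e-07, adjusted p = 0.248 with an estimated correlation) and -0.10 without WT 2. Of 13 mitochondrially encoded genes edgeR called 0, and 0 adjusted over the list alone, with 4 lower at an unadjusted p under 0.05 and 0 called by DESeq2. Their median was -0.21 (camera adjusted p = 0.000225, adjusted p = 0.362 with an estimated correlation, camera adjusted p = 0.774 with the lane as a block).

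Other clusters are given as counts of genes called by edgeR. In granulocyte progenitor-like cluster 4, 523 of 11782 genes changed, 218 of them down, against 209 with the lane as a block, 131 without WT 2 and 150 without WT 3. In megakaryocyte-like cluster 6, 91 of 10061 changed, 74 up and 17 down, against 49 without WT 1 and 45 without WT 3. In cluster 7, 441 of 9977 changed, 277 up and 164 down, against 260 with the lane as a block, 242 without WT 1 and 253 without WT 2. In basophil, mast cell and eosinophil-like cluster 8, 606 of 9806 changed, 289 up and 317 down, against 399 without mutant 1, 228 without WT 1 and 244 without WT 2. In cluster 9, 22 of 8587 changed, 17 up and 5 down, against 3 with the lane as a block and 95 without mutant 4; without mutant 2, mutant 5, WT 1, WT 2 and WT 3 the counts were 12, 14, 14, 7 and 3. In erythroid-like cluster 10 only 2 mutant mice had 20 or more cells, and 52 of 11502 genes changed, 26 up and 26 down, against 11, 4 and 16 without WT 1, 2 and 3.

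Erythroid-like cells were scarce in mutant mice. The share of cells in cluster 10 was 0.421% ± 0.136 in mutant (SD, n = 6, range 0.20% to 0.546%) and 11.5% ± 1.09 in WT mice (SD, n = 3, range 10.3% to 12.5%), 27.2-fold lower (exact two-sided permutation p = 0.0119, adjusted p = 0.0397). The difference was -10.9 and -11.0 percentage points inside lanes 2 and 3. Megakaryocyte-like cells were more frequent: the share of cells in cluster 6 was 6.58% ± 1.00 against 4.62% ± 0.331 (exact permutation p = 0.0238, adjusted p = 0.0397; 2.16 and 0.803 points inside lanes 2 and 3). The share of cells in cluster 9 was 2.45% ± 0.897 against 4.97% ± 0.819 (exact permutation p = 0.0119, adjusted p = 0.0397; -2.74 and -1.63 points inside lanes 2 and 3). In neutrophil-like cells no difference passed: the share of cells in cluster 3 was 16.0% ± 7.13 against 14.1% ± 5.38 (exact permutation adjusted p = 0.690; 6.90 and 10.7 points inside lanes 2 and 3). Without mutant 5 the difference was -0.15 points. With 84 splits of the mice the smallest exact p is 0.0119, and it rises with fewer mice. Leaving out any of mutant 1, 4 or 6 or any WT mouse took all 3 adjusted p over the threshold (up to 0.179). Leaving out mutant 2 took that of cluster 6 (0.0510). Among the cells outside cluster 10, the differences for clusters 6 and 9 did not pass (exact permutation adjusted p = 0.107 and 0.0536). The sorting gates set these shares in part, and their mix per mouse was not given. Outside cluster 1, the share of cluster 10 was 0.609% against 14.2%. By closest deposited reference profile, CFU-E-like cells made up 0.0572% against 4.93%, pre-CFU-E-like cells 0.336% against 5.23% and short-term stem cell-like cells 17.8% against 9.73% (exact permutation adjusted p = 0.0283 for each). Those deposited as BEMP (3.23% against 7.21%), PreGMFlt3Pos (2.75% against 4.90%) and GMP_IRF8int (5.53% against 2.19%) had the same adjusted p.

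**Figure D4:**
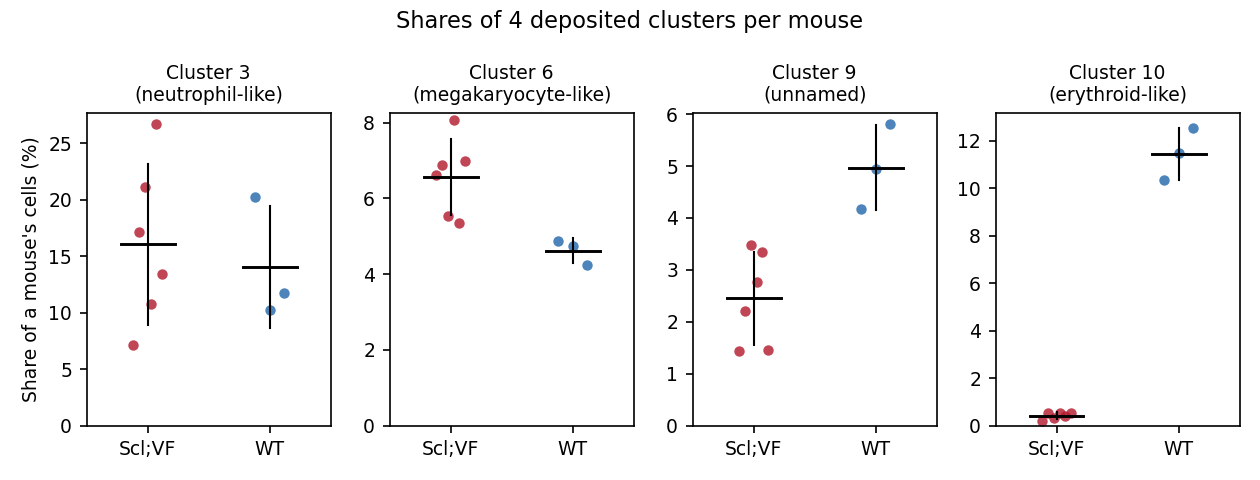
Share of each mouse's cells (percent, axes from 0) in clusters 3, 6, 9 and 10, with each point a mouse, the line the mean and the bar the SD. Cluster 10 lies between 0.20% and 0.546% in mutant mice and between 10.3% and 12.5% in WT mice.

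By the deposited phase calls, more mutant cells were in G0 and fewer in S phase. In all cells, G0 held 30.1% ± 2.60 against 20.3% ± 3.8001 and S phase 3.64% ± 0.458 against 6.03% ± 0.134 (SD, n = 6 and n = 3; exact two-sided permutation adjusted p = 0.0298 for each). G1, G2 and M did not pass (42.4% against 46.3%, 20.3% against 23.2% and 3.52% against 4.14%; exact permutation adjusted p = 0.0992, 0.179 and 0.214). Inside cluster 1 none passed, with S phase at 1.80% against 3.00% and G2 at 8.73% against 10.7% (exact permutation adjusted p = 0.0595 for each). Depth differed between mice, and with cells thinned to 5000 UMIs and scored anew no phase passed, G1 standing at 29.2% against 22.8% (exact permutation adjusted p = 0.107). The cell mix enters the shares in all cells and was not separated. Cluster 1, larger in mutant mice (31.1% against 19.2% of cells), had 56.9% against 49.3% in G0. Free RNA also enters phase calls, and no cycling is read from them alone.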

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

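Among the tests in this part, those without the cells of cluster 10, with a term for hashtag 3, inside single fine clusters, in cells closest to a short-term stem cell profile and of the share of cluster 10 outside cluster 1 were chosen only after the data had been seen, the last 2 after their results were seen.

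Single mice stood apart from their group in 6 of 125 groups of mouse values tested, where chance gives about 1 in 20. In all cells Egr1 was 17.1 CPM in mutant 4 against 27.2 to 28.4 in the other mutant mice, and Irf7 was 3.95 CPM in mutant 1 against 2.65 to 3.07. In cluster 1 Irf7 was 13.9 CPM in mutant 1 against 8.91 to 9.93. In cluster 2 Gm43305 was 14.6 CPM in mutant 5 against 23.2 to 27.5, and Irf7 was 1.59 CPM in mutant 4 against 0.376 to 0.679. In cluster 3 Socs2 was 1.64 CPM in mutant 4 against 0.0460 to 0.603.

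The change differed between clusters by a test of the difference for several named genes, with the clusters drawn from the same 9 mice. From cluster 1 to cluster 2 the log2 change differed by -0.95 for Socs1 (edgeR adjusted p = 0.0206), 0.88 for Pim1 (9.6e-06), 1.19 for Ifitm1 (0.00384), 2.15 for Dntt (0.0329), 1.46 for Ighm (7.31e-10), -0.77 for Nedd4 (2.03e-11) and -0.59 for Blvrb (0.000152). From cluster 1 to cluster 3 it differed by -1.20 for Socs1 (edgeR adjusted p = 0.0252), 0.77 for Pim1 (0.000871), 0.69 for Ighm (0.00325), 2.18 for Clu (0.000439) and 0.80 for Fkbp11 (0.000559). From cluster 1 to cluster 5 it differed by 0.35 for Pim1 (edgeR adjusted p = 0.000468), 0.88 for Ifitm1 (0.0342), 0.58 for Ighm (3.57e-05) and 0.61 for Ffar2 (0.00511). From cluster 2 to cluster 3 it differed by 0.77 for Nedd4 (edgeR adjusted p = 1.29e-06).

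The fall of erythroid genes in all cells went with the scarcity of cluster 10. Over the 22 fallen members measured in both, the median fell from -3.21 with all cells to -1.09 without cluster 10 cells, 0.338 of its size, which is what fewer cells of that cluster predict for most of the fall, though 9 of the 22 still passed. The share of cluster 10 outside stem cell-like cluster 1 was 23.3-fold lower in mutant mice with no overlap. This cannot decide on another mix of sorting gates, which stays open, as the mix per mouse was not given. The members measured had medians of -0.38 in cluster 7, -0.60 in cluster 2, -0.35 in cluster 3, -0.18 in cluster 6 and 0.0022 in cluster 1, and free RNA of erythroid cells in them was not tested. That the mutant genotype itself may lower erythroid cells stays open as a hypothesis.

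The fall of lymphoid-primed genes in cluster 1 was tested against a shifted cell mix and the lanes. Camera found the list lower in each of the 4 fine clusters of cluster 1 alone, with medians of -0.55, -1.13, -0.39 and -0.85 in fine clusters 1, 4, 9 and 11, so another mix of these fine clusters is argued against as the whole cause. For the 8 fallen members the test of lanes could not decide. With the lane as a block their median kept 0.777 of its size, single members 0.684 to 1.13 of theirs, and 5 still passed. That median lay between the sizes set beforehand as arguing for and against lanes. A part due to lanes stays open, and lanes as the whole cause were not excluded. In cells closest to a short-term stem cell profile the list did not pass (-0.14, camera adjusted p = 0.779), so a different mix of cells inside the fine clusters stays open. The genotype stays open as a hypothesis.

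The rise of immediate early and heat shock genes in cluster 1 could come from handling. A term for hashtag 3 left 0.906 of the median of the 5 risen members, and 5 still passed, which argues against handling that goes with that hashtag as the whole cause for these 5. It stays open for other members: Hspa1a was 18.5, 53.4 and 51.3 CPM in mutant 1 to 3 and 13.5 in WT 1, the mice of hashtag 3, and lower in every other mouse, and Fos was highest in mutant 1 to 3. The mice of hashtag 3 were also those with Y-linked transcripts, so handling that goes with this hashtag cannot be told apart from sex. With the lane as a block the list kept its call. The 5 risen members kept 0.809 of their median, and single ones 0.797 to 1.12 of theirs. This median reached the size set beforehand as arguing against lanes, but not every one of the 5 did. Only 1 of them still passed, so the test could not decide on lanes. Handling that differed between groups in every lane was not tested, and the genotype stays open as a hypothesis.

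Chance assignment of the 9 mice was tested with the 84 splits into 6 and 3. It is unlikely, though not excluded with 84 splits, for all cells (3926 genes, at most 38 in another split) and cluster 1 (587 and 4). The same holds for cluster 2 (465 and 7) and cluster 5 (338 and 16). In each, only the real split was as large. The others mix the genotypes, so the gap in counts is no measure of certainty. For cluster 3, with 150 genes, 2 of the 84 splits were as large, a share under 0.05. The other gave 430 genes with mutant 3, mutant 5 and WT 1 as the smaller group, which points to a structure of these samples in cluster 3 apart from genotype. These mice had the highest shares of cells in cluster 3 (21.1%, 26.7% and 20.2%, against at most 17.1% in the others). It does not follow a lane, since mutant 3 was in lane 4 and the others in lane 3. With the lane as a block cluster 3 gave 30 genes.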

How the results depend on the processing

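The settings with lanes 2 and 3 only, a term for hashtag 3, without the cells of cluster 10, by closest profile, in fine clusters, outside cluster 10 and with thinned phase scores were chosen only after the data had been seen, and so were the tests under them. Of the values of single genes, 1538 kept their direction and their side of the threshold, 126 lost the call, 4 gained it and 13 turned. Of the list values 684 kept both, 103 lost the call, 1 gained it and 15 turned. Of the counts of genes 149 stayed within 1.5 times and 88 did not. Genes named only as members of a list, genes other than Socs2 and lists of clusters 6 and 7 and, save without cluster 10, the other constructs were not followed. Of the genes and lists followed, the lane as a block changed no call other than those printed beside a result in the report or here. With edgeR's RLE factors, 50 cells per mouse or a UMI minimum that left out 41 cells, all values of the genes followed kept their direction and call. The median change of all genes was at most 0.0114 in size in the fits reported for all cells and clusters 1, 2, 3 and 5. Depth limits cluster 10, where 2 mutant mice had at least 20 cells. For the changes below the cause was not tested, apart from settings that hold fewer mice, cells or genes by construction.

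With the lane as a replicate block the counts of changed genes were 2349 in all cells. In clusters 1, 2, 3, 4, 5, 7 and 9 they were 203, 84, 30, 209, 82, 260 and 3. As in the report, the calls of Jak2 in all cells (-0.10) and Socs2 in cluster 5 (1.71) were lost. Jak2 turned in clusters 1, 2 and 5 (0.18, 0.062 and 0.022). With lanes 2 and 3 only the counts were 2173 in all cells. In clusters 1, 2, 3, 4, 5, 7 and 8 they were 185, 100, 16, 126, 72, 222 and 322. Calls were lost in all cells for Jak2 (-0.15), Prg2, Pim1, Rgs1 and Ly6a, and in cluster 1 for Dntt, Gm43305 and Socs1. Calls were also lost in cluster 2 for Pim1 and Gm43305, and in cluster 3 for Clu, Pim1, Ncam1, Lars2 and Socs3. Jak2 turned in cluster 1 (0.12) and cluster 2 (0.0099). With a change of at least 2-fold the counts were 624 in all cells. In clusters 1 to 10 they were 118, 65, 29, 48, 58, 39, 109, 71, 12 and 27. With no low-count filter they were 941, 750, 535, 521, 174, 156 and 561 in clusters 1, 2, 3, 5, 6, 9 and 10. With at least 50 counts in every WT mouse they were 360, 27, 246 and 21 in clusters 1, 6, 7 and 10. With equal cell numbers they were 230, 78, 208, 219, 251, 270 and 6 in clusters 2, 3, 4, 5, 7, 8 and 9. The calls of Ifitm1, Clu and Lars2 in cluster 3 and Itga1 in cluster 2 were lost, and Socs1 in cluster 3 turned (0.11). By DESeq2 the counts were 341, 240, 372, 68 and 290 in clusters 3, 7, 8, 9 and 10. Cluster 3 gave 48 with library size only, cluster 9 gave 41 with a term for hashtag 3, and cluster 10 gave 424 with at least 10 cells per mouse. Without the cells of cluster 10 all cells gave 1247, and Jak2 stood at -0.20. For cluster 1 the count was 157 by closest profile a short-term stem cell, with Irf7 at 0.14, and 32 by closest profile a long-term stem cell, 9 of them also called in cluster 1 and 4 of these in the same direction, with Pim1 at -0.26. It was 105 in fine cluster 1 alone, with Irf7 at 0.18, 40 in fine cluster 9 and 197 in fine cluster 11, where Irf7 passed (-0.90), and Jak2 in fine cluster 4 stood at 0.10.

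With an estimated correlation 3 lists passed in all cells, 2 in cluster 1, 0 in cluster 2, 0 in cluster 3 and 3 in cluster 5. Lists that lost their call keep their median log2 change, in brackets. In all cells they were B cell (-1.28), G2 and M phase (-0.18), glycolysis (0.31), stem cell (0.51), immediate early genes (0.52), lymphoid-primed (-0.37), megakaryocyte (0.44), mitochondrial genes (-0.28), monocyte and dendritic cell (-0.17), negative JAK-STAT regulators (0.053), neutrophil (0.29), S phase (-0.14) and TNF and NF-kB response (0.28). In cluster 1 they were G2 and M phase (-0.28), glycolysis (0.15), stem cell (0.26), immediate early genes (0.77), megakaryocyte (0.28), mitochondrial genes (-0.18), negative JAK-STAT regulators (-0.048), T and natural killer cell (-0.78) and type I interferon response (-0.070). In cluster 2 they were erythroid (-0.59), glycolysis (0.15), haem and globins (-0.032), stem cell (-0.045), immediate early genes (0.30), JAK-STAT5 targets (0.15), mitochondrial genes (-0.28) and neutrophil (0.13). In cluster 3 they were G2 and M phase (-0.099), glycolysis (0.14), stem cell (0.12), immediate early genes (0.41), JAK-STAT5 targets (0.21), mitochondrial genes (-0.35) and type I interferon response (-0.19). In cluster 5 they were G2 and M phase (-0.16), glycolysis (0.17), stem cell (0.12), immediate early genes (0.73) and mitochondrial genes (-0.21).

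By fry 2 lists passed in cluster 2 and 2 in cluster 3. It lost, with the median in brackets, B cell (-1.28) and neutrophil (0.29) in all cells, mitochondrial genes (-0.18) and type I interferon response (-0.070) in cluster 1, erythroid (-0.59), glycolysis (0.15), stem cell (-0.045), immediate early genes (0.30), mitochondrial genes (-0.28) and neutrophil (0.13) in cluster 2, G2 and M phase (-0.099), stem cell (0.12), immediate early genes (0.41), mitochondrial genes (-0.35) and type I interferon response (-0.19) in cluster 3 and G2 and M phase (-0.16) and mitochondrial genes (-0.21) in cluster 5 (fry adjusted p 0.0646 to 0.597). With the lane as a replicate block camera lost, with the median in brackets, B cell (-0.87), lymphoid-primed (-0.21) and mitochondrial genes (-0.077) in all cells, glycolysis (0.051) and type I interferon response (-0.078) in cluster 1, haem and globins (-0.037) in cluster 2, stem cell (0.028) and mitochondrial genes (-0.10) in cluster 3 and mitochondrial genes (-0.016) in cluster 5. The median turned for mitochondrial genes (0.085) in cluster 1, erythroid (0.070) in cluster 2 and G2 and M phase (0.033) in cluster 3. Without the cells of cluster 10 camera lost haem and globins (0.0021), neutrophil (0.020), S phase (-0.030) and TNF and NF-kB response (0.013) in all cells. In fine cluster 9 alone 7 lists passed, camera lost glycolysis (0.060), stem cell (-0.038), megakaryocyte (0.21), mitochondrial genes (-0.093) and T and natural killer cell (-0.30), and type I interferon response (0.087) turned. In fine cluster 1 alone the median turned for stem cell (-0.015), megakaryocyte (-0.019) and T and natural killer cell (0.23). Fine cluster 11 alone lost mitochondrial genes (-0.15) and T and natural killer cell (-0.92), and fine cluster 4 alone T and natural killer cell (-0.89) and type I interferon response (-0.043).

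Leaving out each mouse in turn, the counts of changed genes ran from 2572 to 3963 in all cells. In clusters 1 to 5 they ran from 322 to 765, 199 to 682, 19 to 169, 131 to 574 and 178 to 484. In clusters 6 to 10 they ran from 45 to 113, 242 to 431, 228 to 604, 3 to 95 and 4 to 16. The log2 change ran from -0.39 to -0.19 for Jak2 in all cells, -0.21 to 0.00051 for Jak2 in cluster 1, -0.0015 to 0.51 for Cish in cluster 2, -0.92 to 0.085 for Irf7 in cluster 3 and 2.32 to 2.61 for Socs2 in cluster 5. The median of a list ran from -0.37 to -0.13 for monocyte and dendritic cell in all cells, -0.044 to 0.080 for type I interferon response in all cells, 0.093 to 0.17 for glycolysis in cluster 1, -0.25 to -0.12 for mitochondrial genes in cluster 1, -0.81 to -0.29 for T and natural killer cell in cluster 1, -0.14 to 0.019 for type I interferon response in cluster 1, -0.080 to -0.0021 for haem and globins in cluster 2, 0.12 to 0.21 for JAK-STAT5 targets in cluster 2, -0.036 to 0.14 for neutrophil in cluster 2, -0.20 to 0.00074 for type I interferon response in cluster 2, -0.23 to 0.080 for G2 and M phase in cluster 3 and -0.12 to 0.0097 for type I interferon response in cluster 5. The differences in share ran from -0.146 to 5.05 percentage points in cluster 3 and 1.66 to 2.21 in cluster 6. They ran from -2.92 to -2.10 in cluster 9 and -11.6 to -10.5 in cluster 10.

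With lanes 2 and 3 only the differences in percentage points for the shares of clusters 6, 9 and 10 were 1.51, -2.19 and -11.0. The exact permutation adjusted p was 0.167 for each, as 10 splits of 2 against 3 mice are too few to pass. Lane 3 alone gave 10.7, 0.803 and -1.63 for the shares of clusters 3, 6 and 9. As a centred log ratio the share of cluster 9 differed by -0.445 (adjusted p 0.119). Of the cells outside cluster 10, the shares of clusters 6 and 9 differed by 1.395 and -3.16. The phases were also scored anew in 3 classes. The unthinned differences in all cells were -3.41 for S, -5.78 for G2 or M and 9.19 for G0 or G1. Those of G2 or M and of G0 or G1 passed. In cluster 1 the differences were -1.98, -4.38 and 6.35, and none passed. With thinned cells the differences for S, G2 or M and G0 or G1 were -1.62, -4.81 and 6.43 in all cells. In cluster 1 they were -1.52, -3.67 and 5.18, and none passed in either. Single lanes were not fitted for genes: none held the 2 mice per group set as condition. A fit of only the groups compared holds all mice, and no clustering was run here.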

Other observations

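In this part the choice of clusters 6 and 7 and of the genes named there was made only after the values were seen, and their tests are those fixed for every cluster.

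In cluster 7, an unnamed cluster, megakaryocyte genes were higher and erythroid genes lower in mutant mice. Of 19 megakaryocyte genes 11 rose, 14 adjusted over the list alone (median 0.75, camera adjusted p = 8.21e-18, adjusted p = 0.0103 with an estimated correlation), among them platelet factor 4 gene Pf4 (63.1 against 31.4 CPM), Itgb3 (1.99) and Selp (1.93). Of 18 erythroid genes 6 fell, 11 adjusted over the list alone (median -0.33, camera adjusted p = 1.94e-16, adjusted p = 0.0103 with an estimated correlation), among them Car1 (380 against 950 CPM), Ermap (-1.25) and Klf1 (-0.45). Of 17 stem cell genes 10 rose, 13 up and 1 down adjusted over the list alone (median 0.59, camera adjusted p = 9.68e-13, adjusted p = 0.0103 with an estimated correlation), among them Esam (1.54) and Mecom (1.11). Of the 10 leading genes of cluster 7, 7 changed inside it, so a shift in which cells fell into the cluster was not separated from a change within cells.

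In megakaryocyte-like cluster 6, stem cell and JAK-STAT5 target genes were higher. Of 19 stem cell genes 3 rose, 8 adjusted over the list alone (median 0.36, camera adjusted p = 3.32e-10, adjusted p = 0.0385 with an estimated correlation), namely Ltb (1.68), Ifitm1 (1.03) and Rbpms (0.92). Of 15 JAK-STAT5 targets 4 rose, Socs2 (2.51), Podxl (2.61), Cish (1.75) and Pim1 (0.70), and Ccnd1 (-1.11) fell, 6 and 1 adjusted over the list alone (median 0.39, camera adjusted p = 1.00e-08, adjusted p = 0.0268 with an estimated correlation). The list of megakaryocyte genes itself did not pass there (camera adjusted p = 0.753).

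Transcripts of other constructs were read in both groups. CreERT2 measured 26.5 ± 1.99 CPM in mutant and 22.5 ± 1.37 CPM in WT mice (0.24, edgeR adjusted p = 0.0204), and CARLIN, a lineage barcode construct, 14.9 ± 1.83 and 10.4 ± 0.542 CPM (0.52, edgeR adjusted p = 0.00198). Without cluster 10 cells neither passed (0.02 and 0.33, edgeR adjusted p = 0.904 and 0.0627). CARLIN was higher in cluster 7 (0.91, edgeR adjusted p = 0.000546) and cluster 8 (1.31, edgeR adjusted p = 7.51e-05), and passed in no other cluster.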
